A study of Homo sapiens with 16 samples.

How the data were processed

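The series is a RIP-seq study of cells labelled UM-SCC-1, in which RNA pulled down with Strep-tagged vector, ALKBH5 or RBM33 was sequenced beside input RNA. Per the labels' protocols, cells were infected with lentivirus, selected and lysed in a buffer with the detergent NP-40. Stranded total RNA libraries were made with the Takara SMARTER Pico kit from fragmented RNA and sequenced on an Illumina NovaSeq. Such libraries are made from total RNA with random priming, so noncoding and nonpolyadenylated RNAs are measured. Groups and replicate numbers were taken from the sample titles: 3 pull-down and 3 input libraries each for vector and ALKBH5, and 2 and 2 for RBM33. Nothing in the labels says that replicates came from separate cultures, so the authors' p-values may measure only technical spread.

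Per the submitters' processing notes, the tools were cutadapt 1.18, HISAT2 2.1.0, featureCounts, Subread 1.6.4 and edgeR 3.24.3, with the human build hg38. The annotation release, the low-count filter and the strand setting of the counting are not given in the sources used here, so reads of a gene and an antisense partner may be mixed. Per the file headers, the authors' deposited tables give for each gene a log2 fold change and an average log2 CPM over the libraries of the fit. The F statistic in the authors' deposited tables is a score without fixed range. The p-value in the authors' deposited tables belongs to that F statistic, and the adjusted p-value is its Benjamini-Hochberg adjustment. Recomputing that adjustment over the 16324 genes gave the deposited values, so no gene was dropped after the adjustment. Per the file headers, each gene also has a length in bases, position, strand and annotated type. The listed length is not that of 1 mRNA: protein-coding genes reach 55886 bases, and ribosomal protein genes have a median of 3159, so it is called listed gene length. Gene names are those in the tables; symbols of fixed lists that were missing were also searched under older symbols. How the tables were normalized is not stated. No test was made of differences in fold change between them, because they hold no values per library.

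The contrast and its direction are not stated in the tables. Both are labelled siCtrl, read here as control siRNA, which no sample title names. Library numbers below are those of the sample titles, and it is not stated that the tables were made from exactly these libraries. The total degrees of freedom behind each gene were worked out from its F and p-value for genes with F over 4 and average log2 CPM of at least 5. In the ALKBH5 table, 53 of 4343 such genes fell below the 8 residual degrees of freedom that a fit of 12 libraries in 4 groups, vector included, would leave. In the RBM33 table, 51 of 4300 fell below the corresponding 6, and 1 fell below the 3 of RBM33 pull-down against vector pull-down. For ALKBH5, pull-down against vector pull-down would leave 4, the same as against its own input, and no gene fell below it. None fell below the 4 (ALKBH5) and 2 (RBM33) that a fit of a bait's pull-down against its own input would leave. Degrees of freedom therefore leave open a contrast with the vector pull-down for ALKBH5, and speak against it for RBM33 by 1 gene only. The size of the bait's own value bears on the same question: average abundance of ALKBH5 mRNA was higher by 5.62 on the log2 scale in its own table than in the other of the authors' deposited tables, and that of RBM33 mRNA by 6.09. A contrast of bait pull-down with vector pull-down, which lacks the overexpressed bait, would be of about that size or larger. The log2 fold changes in the authors' deposited tables were 1.28 and 3.41. These values do not bear on pull-down over input corrected for that of the vector, since the bait is then in both of its own fractions. Only the degrees of freedom of the 4-group fit speak against that contrast. Bait pull-down over own input is therefore the likely contrast of both tables, which then share no library, although no label states it. The direction stays open: each bait's own mRNA was positive in its own table, but both arms of such a contrast carry the overexpressed bait, and published ALKBH5 targets went both ways in the authors' deposited tables: DDIT4 and FOXM1 were negative in both, and NEAT1, FOXO1 and PER1 positive in both. Signs are given as in the tables.

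The planned analysis was a count model over libraries with the vector pull-down as background. Since the tables hold the authors' comparisons, the fallback fixed with it was used: genes were counted as called at the authors' adjusted p under 0.05, with the sign of the log2 fold change as direction. Calls were compared between the tables with the overlap of independent lists (the product of both call numbers over the genes tested) and a two-sided Fisher's exact test. Fold changes were compared with Pearson and Spearman correlations across genes. For each of 19 gene lists fixed before the data were examined, the share of members called in each direction was tested against all other genes with a two-sided Fisher's exact test. The 38 p-values per table were adjusted together by Benjamini-Hochberg. These list tests treat genes as independent, although members of a list can vary together in the same libraries. Their p-values may therefore overstate the evidence and do not measure spread between replicates. The list median was placed among 10000 random lists of the same size, matched in 20 bins of abundance. A further match, chosen after the length trend was seen, replaced each member by 1 of its 50 nearest protein-coding genes in listed length and abundance. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the members' deposited p-values only. Genes named in the text are the baits, DDIT4, the 10 genes of largest positive and of largest negative log2 fold change among called genes of at least median abundance with a gene symbol, and the 4 members of each list with the smallest adjusted p. MT-ND6, ROBO3, TM2D1 and cell type markers given as listed or not listed, or by abundance, were named after their values were seen. As a rule for human samples, transcripts that report on sex are left out of the named genes and the plots.

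Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The list, overlap and adjustment code was tested on simulated data over 16324 genes. With no list effect, 5% of 40 simulated lists of 30 genes fell outside the middle 95% of random lists, and all of 40 lists of 20 genes shifted by 1 log2 unit were found above it. With a simulated length trend, 5% of 40 lists of short genes fell outside the middle 95% after the match on length and abundance.

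Alternatives were a stricter threshold of 0.01, a minimum of 1 log2 unit, only genes of at least median abundance, and leaving out mitochondrial, histone, small noncoding and pseudogene rows. Chosen after seeing the data were protein-coding genes only, identical rows counted once, and fold changes with abundance, length and gene type regressed out. In 3349 genes the annotated span overlaps another listed gene on the same strand, and 9 rows repeat the statistics of another row, so values of overlapping genes, paralogs and pseudogenes are uncertain. The libraries' depth is unknown from the tables, which leaves no interval for counting error.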

Results

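RNA bound by tagged proteins was sequenced (RIP-seq) from cells labelled UM-SCC-1, an established line of head and neck squamous cell carcinoma. The baits carried a Strep tag, a short peptide that binds StrepTactin beads, and were ALKBH5, an enzyme that removes the methyl mark m6A from RNA, or RBM33, an RNA-binding protein. An empty vector (Vec) with the tag served as the control. The series has 16 libraries in 6 groups: 3 pull-down and 3 input libraries for Vec, 3 and 3 for ALKBH5, and 2 and 2 for RBM33. The files used here were 2 tables of the authors' own comparisons, 1 for each bait, and both list the same 16324 genes. Both comparisons are labelled siCtrl, read here as control siRNA, a treatment that no title of the 16 libraries names. They give a log2 fold change, an average log2 CPM, an F statistic and p-values per gene and no value per library. The depth of each library is therefore unknown here, and no standard deviation or n stands beside the values.

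The tables do not state which groups were compared or which way the ratio runs, so the direction of the values is not settled here. The bait genes themselves give a hint. ALKBH5 mRNA (ENSG00000091542, chromosome 17, 18183078 to 18209954, hg38) had a log2 fold change of 1.28 in the authors' deposited table for ALKBH5 (adjusted p = 0.00158). It stood at -0.21 in the authors' deposited table for RBM33 (adjusted p = 0.245). RBM33 mRNA (ENSG00000184863, chromosome 7, 155644451 to 155781485) was positive in both of the authors' deposited tables, at 3.41 for RBM33 (adjusted p = 5.14e-05) and 1.17 for ALKBH5 (adjusted p = 7.1e-06). Average abundance of ALKBH5 mRNA was 49.2 times higher in its own table than in the other of the authors' deposited tables. That of RBM33 mRNA was 68.1 times higher in the authors' deposited table for RBM33. Whether the tables were normalized together is not stated. Each bait's mRNA being positive would fit more RNA in the pull-down than in the matching input, but both arms then carry the overexpressed bait, so this does not fix the sign. Values are therefore described only as positive or negative, as the tables give them. The mRNA of DDIT4 encodes a stress-induced inhibitor of mTOR complex 1 and is known as an ALKBH5 target. It was negative in both of the authors' deposited tables, at -0.72 (adjusted p = 0.000466) for ALKBH5 and -0.87 (adjusted p = 0.00129) for RBM33. The published targets as a list do not settle the sign either: 4 of 12 were positive and 2 negative for ALKBH5, and 4 and 3 for RBM33, in the authors' deposited tables. If, as is likely from the degrees of freedom and the baits' own values, the vector libraries entered neither fit, background binding to the beads was not subtracted.

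The first comparison concerns the RNAs that associate with ALKBH5. Small nucleolar RNAs, nuclear long noncoding RNAs and the mRNAs of large chromatin regulators were positive, and the mRNAs of ribosomal proteins, replication-dependent histones and the mitochondrial genome were negative. Of 16324 genes in the authors' deposited table for ALKBH5, 4978 were positive and 4745 negative at an adjusted p under 0.05, and 6601 were not called. By gene type, 85 of 90 small nucleolar RNAs were positive in the authors' deposited table, with a median log2 fold change of 4.06. Of 63 small nuclear RNAs, 43 were positive in the authors' deposited table, with a median of 1.45. Among 1671 long noncoding RNAs, 801 were positive and 78 negative in the authors' deposited table (median 1.15). The 13210 protein-coding genes split into 3632 positive and 4397 negative calls in the authors' deposited table (median -0.08).

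Individual small RNAs had the largest positive values among genes of at least median abundance. SNORA66 reached 6.45 (adjusted p = 0.000552), SNORA73A 6.33 (adjusted p = 5.4e-06) and SNORA22 6.30 (adjusted p = 8.74e-06) in the authors' deposited table for ALKBH5. These H/ACA box RNAs act in pseudouridylation or processing of ribosomal RNA. Each lies inside a listed host gene on the same strand (RPL5, RCC1 and SNHG3, and CCT6P1), so host reads may enter their values. The fixed list of abundant noncoding RNAs had 18 positive and 1 negative of 24 listed members in the authors' deposited table (19 and 2 adjusted over the list alone; Fisher's exact test, adjusted p = 3.79e-05). Its median of 1.97 was higher than those of all 10000 abundance-matched random lists. Its members included SNORD3A, the U3 RNA of ribosomal RNA processing, at 4.37, SCARNA2, a guide RNA of Cajal bodies, at 3.91, and RMRP, the RNA of RNase MRP, at 2.48 in the authors' deposited table. Nuclear long noncoding RNAs had 12 of 14 listed members positive and none negative in the authors' deposited table for ALKBH5 (12 adjusted over the list alone, median 1.66, Fisher's exact test, adjusted p = 0.000115). KCNQ1OT1, which silences an imprinted cluster on chromosome 11, stood at 5.68 (adjusted p = 1.32e-09) in the authors' deposited table. NEAT1, the scaffold of paraspeckles (chromosome 11, 65422774 to 65445540), stood at 5.10 there (adjusted p = 4.77e-09). PVT1, transcribed next to MYC, had 2.92 (adjusted p = 1.67e-08) in the authors' deposited table for ALKBH5.

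Chromatin regulators with long mRNAs had 20 of 24 members positive and none negative in the authors' deposited table for ALKBH5 (21 adjusted over the list alone, median 1.19, Fisher's exact test, adjusted p = 6.93e-07). The histone H3 lysine 4 methyltransferases KMT2D (2.97, adjusted p = 1.23e-08) and KMT2B (2.38, adjusted p = 2.46e-08) led the list in the authors' deposited table. EP400, an ATPase of a chromatin-remodelling complex, had 1.84 and ARID1B, a subunit of the BAF remodelling complex, 1.81 in the authors' deposited table. Zinc finger genes of the ZNF family had 213 positive and 31 negative of 423 listed members in the authors' deposited table (213 and 30 adjusted over the list alone, median 0.68, Fisher's exact test, adjusted p = 8.11e-17). ZNF460 stood at 2.57 and ZNF276 at 2.22 in the authors' deposited table. Serine and arginine rich proteins and other splicing factors had 14 positive and 4 negative of 26 members in the authors' deposited table (15 and 5 adjusted over the list alone, adjusted p = 0.0385 by Fisher's exact test). Its positive members included the RNA helicases DDX17 (3.06, adjusted p = 1.41e-08) and DDX5 (2.43, adjusted p = 6.41e-08), PNISR (2.21) and the splicing factor RBM5 (1.79) in the authors' deposited table. Counting calls of at least 1 log2 unit ended the splicing factor call in the authors' deposited table for ALKBH5 (adjusted p = 0.256).

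Ribosomal protein, histone and mitochondrial mRNAs lay on the other side. Cytosolic ribosomal protein mRNAs were negative for 79 of 82 genes and positive for 0 in the authors' deposited table for ALKBH5 (79 adjusted over the list alone, median -1.59, Fisher's exact test, adjusted p = 3.16e-37). RPL22L1 stood at -2.80, RPL26L1 at -2.45 and RPL22 at -2.36 in the authors' deposited table. Replication-dependent histone mRNAs end in a stem-loop instead of a poly(A) tail. They were negative for 45 of 50 genes in the authors' deposited table (45 adjusted over the list alone, median -1.78, Fisher's exact test, adjusted p = 3.14e-18), and H2AC21 had -2.83 and H2AC4 -2.42. The mitochondrial mRNAs were negative for 12 of 13 genes in the authors' deposited table (12 adjusted over the list alone, median -1.74, Fisher's exact test, adjusted p = 1.63e-05). MT-CO2 and MT-CO1, both subunits of cytochrome c oxidase, stood at -2.31 and -2.17 in the authors' deposited table. MT-ND6, the exception and the mitochondrial mRNA read from the light strand, had -0.05 in the authors' deposited table. Other large negative values in the authors' deposited table for ALKBH5 were KRT10, a keratin, at -3.06 (adjusted p = 6.49e-08), COX17, a copper chaperone of cytochrome c oxidase, at -2.93 (adjusted p = 1.67e-08). The processed pseudogenes RPS23P8 at -3.46 and RPL22P1 at -3.33 in the authors' deposited table can share reads with their parent genes. Mitotic and proliferation mRNAs had 6 positive and 14 negative of 27 members in the authors' deposited table (6 and 14 adjusted over the list alone, adjusted p = 0.0385 for the negative calls by Fisher's exact test). CENPF at 1.61 and ASPM at 1.52, which encode a kinetochore and a spindle pole protein, were positive and CCNB2, a cyclin of mitotic entry, was negative at -1.71 in the authors' deposited table. That list's median of -0.28 was at percentile 73.8 of abundance-matched random lists, so test and median point different ways. The call was lost in the authors' deposited table under each alternative run: at a threshold of 0.01 (adjusted p = 0.0955), with a minimum of 1 log2 unit (adjusted p = 0.885) and among genes of at least median abundance (adjusted p = 0.776).

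Values followed the listed gene length, which is not the length of 1 transcript. Among protein-coding genes the log2 fold change in the authors' deposited table for ALKBH5 correlated with it across genes (Spearman rho 0.41; genes are not independent replicates). The 3303 shortest genes, up to 3313 bases, had a median of -0.74 and the 3303 longest, from 7841 bases, a median of 0.50 in the authors' deposited table. Against protein-coding genes of like listed length and abundance, the medians of chromatin regulators (percentile 99.96 of 10000 random lists) and ZNF genes (percentile 100) stayed high in the authors' deposited table for ALKBH5. Ribosomal protein mRNAs stayed low (percentile 0.01), with a median of -1.59 against -1.34 in lists so matched and -0.78 in lists matched on abundance alone, but histone mRNAs were within the middle 95% of those lists (percentile 4.81).

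The second comparison concerns RBM33. The same classes of RNA stood at the ends of the table: small nucleolar RNAs and chromatin regulator mRNAs were positive, and mitochondrial, ribosomal protein and histone mRNAs were negative. Of 16324 genes in the authors' deposited table for RBM33, 3925 were positive, 4413 negative and 7986 not called. Small nucleolar RNAs were positive for 82 of 90 genes in the authors' deposited table for RBM33 (median 4.16). Small nuclear RNAs were positive for 50 of 63 (median 2.03) and long noncoding RNAs for 598 of 1671 (median 0.85) in the authors' deposited table. Genes annotated as ribosomal RNA were positive for 20 of 24 in the authors' deposited table for RBM33 (median 1.87) and for 2 of 24 in the one for ALKBH5 (median 0.68). These rows hold near-identical values, with quartiles of 1.67 and 1.87 for RBM33 and 0.67 and 0.68 for ALKBH5 in the authors' deposited tables, so they are not separate measurements. That difference was not tested, because the tables hold no values per library.

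SNORA22 had the largest value among named genes of the authors' deposited table for RBM33, 7.01 (adjusted p = 5.08e-07). SNORA71A followed at 6.79 (adjusted p = 2.25e-06), SNORA66 at 6.69 and MIR3648-1, on chromosome 21, at 6.14 in the authors' deposited table. SNORA71A overlaps SNHG17 and MIR3648-1 overlaps FP671120.4 on the same strand, so reads of those genes may enter their values. Abundant noncoding RNAs had 18 positive and 5 negative of 24 members in the authors' deposited table for RBM33 (18 and 5 adjusted over the list alone, median 2.36, Fisher's exact test, adjusted p = 1.1e-06). RNU4-2, the U4 RNA of the spliceosome, stood at 4.77 and SNORD3A at 4.76, whereas the mitochondrial ribosomal RNA MT-RNR2 stood at -3.93 (adjusted p = 1.84e-05) in the authors' deposited table for RBM33. Nuclear long noncoding RNAs had 10 positive and 1 negative of 14 listed members in the authors' deposited table for RBM33 (10 and 1 adjusted over the list alone, median 1.36, Fisher's exact test, adjusted p = 0.000914). PVT1 stood at 2.25, TUG1 at 1.41 and SNHG1, the host gene of several small nucleolar RNAs, at 1.31 in the authors' deposited table.

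Chromatin regulator mRNAs were positive for 22 of 24 genes and negative for 0 in the authors' deposited table for RBM33 (22 adjusted over the list alone, median 1.39, Fisher's exact test, adjusted p = 3.59e-11). KMT2D at 3.27 (adjusted p = 3.67e-06), SETD1B, another lysine 4 methyltransferase, at 2.70, CHD8, a chromatin remodeller, at 1.99 and KMT2C at 1.95 had the smallest p-values of that list in the authors' deposited table for RBM33. ZNF genes had 162 positive and 17 negative of 423 members in the authors' deposited table for RBM33 (157 and 17 adjusted over the list alone, median 0.53, Fisher's exact test, adjusted p = 3.49e-10). ZNF266 had 2.37 and ZNF445 1.85, but ZNF330 had -1.76 in the authors' deposited table. Splicing factors had 14 positive and 2 negative of 26 members in the authors' deposited table for RBM33 (14 and 3 adjusted over the list alone, Fisher's exact test, adjusted p = 0.00318). SRRM2, a large protein of nuclear speckles, had 1.89 and CLK1, a kinase of splicing factors, 1.27 in the authors' deposited table. Extracellular matrix and secreted protein mRNAs had 8 positive and 1 negative of 14 listed members in the authors' deposited table for RBM33 (8 and 1 adjusted over the list alone, Fisher's exact test, adjusted p = 0.0234). LAMA5, a laminin chain, at 3.29 and HSPG2, the basement membrane proteoglycan perlecan, at 2.85 were positive in the authors' deposited table for RBM33. TIMP1, a protease inhibitor, was negative there at -1.30. The same list had 8 positive and 2 negative members in the authors' deposited table for ALKBH5 (8 and 2 adjusted over the list alone), which missed the threshold (adjusted p = 0.0859, Fisher's exact test). With calls at 0.01 or a minimum of 1 log2 unit, the list passed in the authors' deposited table for ALKBH5 (adjusted p = 0.0256 and 0.0115) and no longer passed in that for RBM33 (adjusted p = 0.0548 and 0.0682). Among genes of at least median abundance it passed in neither of the authors' deposited tables (adjusted p = 0.0508 and 0.0757). Its median was at percentile 99.76 of abundance-matched lists for ALKBH5 and at 92.85, within the middle 95%, for RBM33. Whether the baits differ on this list was not tested.

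Mitochondrial mRNAs were again negative for 12 of 13 genes, with a median of -2.43 in the authors' deposited table for RBM33 (12 adjusted over the list alone, Fisher's exact test, adjusted p = 6.99e-06). MT-ATP8 had -3.18, MT-CO2 -2.90 and MT-ND4 -2.79 in the authors' deposited table. Ribosomal protein mRNAs were negative for 79 of 82 genes in the authors' deposited table for RBM33 (79 adjusted over the list alone, median -1.48, Fisher's exact test, adjusted p = 1.06e-39), and RPL22L1 had -2.95. Histone mRNAs were negative for 45 of 50 genes in the authors' deposited table for RBM33 (46 adjusted over the list alone, median -1.62, Fisher's exact test, adjusted p = 1.36e-19), and H2AC21 had -2.75. COX17 at -3.25, SH3BGRL at -2.98 and COX6C, a subunit of cytochrome c oxidase, at -2.93 were other large negative values in the authors' deposited table for RBM33. mRNAs of nuclear export factors had 4 positive and 10 negative of 19 members in the authors' deposited table for RBM33 (4 and 10 adjusted over the list alone, adjusted p = 0.0461 for the negative calls by Fisher's exact test). THOC7, a subunit of the TREX export complex, had -2.19 and the export helicase DDX39B 1.48 in the authors' deposited table. The export list's median of -0.47 was at percentile 44.57 of abundance-matched random lists. The calls for export factors and secreted proteins in the authors' deposited table for RBM33 were lost under each alternative run. Adjusted p was 0.212 and 0.0548 at 0.01, 0.451 and 0.0682 with a minimum of 1 log2 unit, and 0.784 and 0.0757 among genes of at least median abundance. That for splicing factors was lost with a minimum of 1 log2 unit (adjusted p = 0.192).

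Listed gene length gave a like gradient for RBM33 across protein-coding genes (Spearman rho 0.45). Medians were -0.84 for the 3303 shortest and 0.49 for the 3303 longest genes in the authors' deposited table. Matched on listed length and abundance, chromatin regulators and ZNF genes were both at percentile 100 of random lists in the authors' deposited table for RBM33. Ribosomal protein mRNAs were at percentile 0.3 (median -1.48 against -1.31 in lists so matched and -0.85 in lists matched on abundance alone) and histone mRNAs at percentile 37.74.

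Whether ALKBH5 and RBM33 share most of their RNAs is the question that the series' design poses. The positive calls of the authors' deposited tables shared 3509 genes, 70.5% of the ALKBH5 calls and 89.4% of the RBM33 calls. Independent lists would share 1197, a ratio of 2.93. The two-sided Fisher's exact test of that overlap gave an odds ratio of 62.8 and a log10 p of -1825.8, over genes that are not independent of each other. Negative calls of the authors' deposited tables shared 3876 genes, 81.7% of the ALKBH5 calls and 87.8% of the RBM33 calls, against 1283 expected (odds ratio 91.7). By the sample titles RBM33 has 2 libraries per fraction and ALKBH5 has 3. A gene called for ALKBH5 only may therefore be missed for RBM33 and need not differ between the baits. Opposite calls were made for 2 genes, against 2487 expected over both directions, and both were positive for ALKBH5 and negative for RBM33 in the authors' deposited tables. They were ROBO3, an axon guidance receptor (0.53 and -0.71), and TM2D1 (0.44 and -0.50), named here after their values in the authors' deposited tables were seen. No gene was negative for ALKBH5 and positive for RBM33 in the authors' deposited tables, where 1141 were expected, against 1346 for the other direction.

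Fold changes of the authors' deposited tables correlated across all 16324 genes with a Pearson r of 0.872 and a Spearman rho of 0.873 (covariance 1.52), and 86.6% of genes had the same sign. KMT2D (2.97 for ALKBH5 and 3.27 for RBM33), NEAT1 (5.10 and 5.06), RPL22L1 (-2.80 and -2.95) and COX17 (-2.93 and -3.25) show how close the values were in the authors' deposited tables. ANKRD19P, an expressed pseudogene, was among the more distant pairs, at 5.98 for ALKBH5 and 3.50 for RBM33 in the authors' deposited tables. Genes and not binding sites are compared here, and without vector pull-down values the shared calls include any RNA that the beads hold in both experiments. Differences between the baits were not tested, because the authors' deposited tables hold no values per library.

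**Figure D1:**
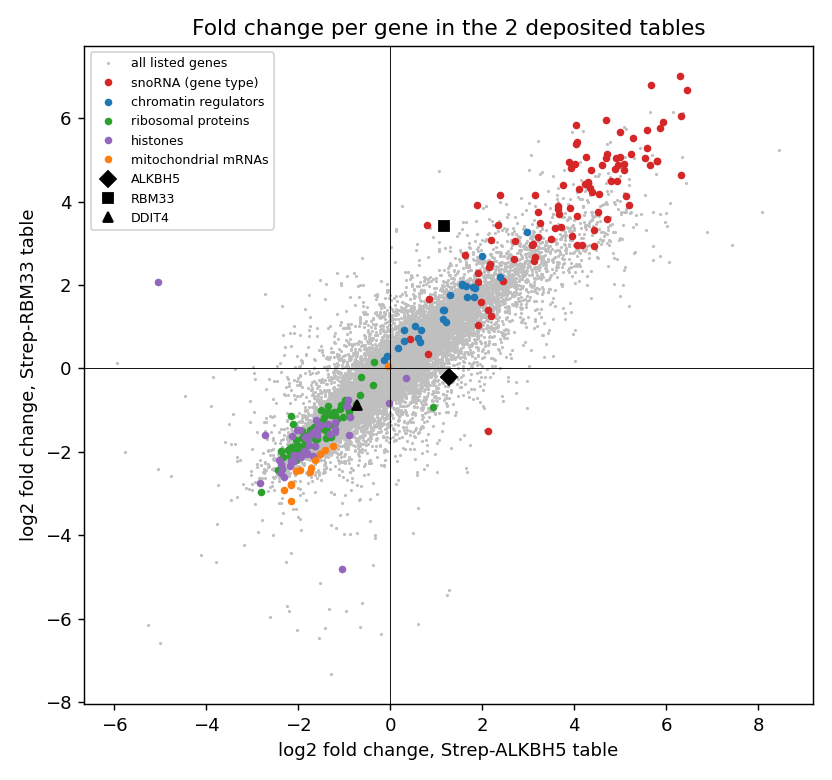
Log2 fold change of listed genes in the authors' deposited table for ALKBH5 (horizontal axis) against that in the table for RBM33 (vertical axis). Genes are grey, with small nucleolar RNAs and the mRNAs of chromatin regulators, ribosomal proteins, histones and the mitochondrial genome in colour. ALKBH5, RBM33 and DDIT4 are black markers. Transcripts that report on sex are not drawn. Points follow the diagonal with a Pearson r of 0.872, and 2 genes had opposite calls.

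**Figure D2:**
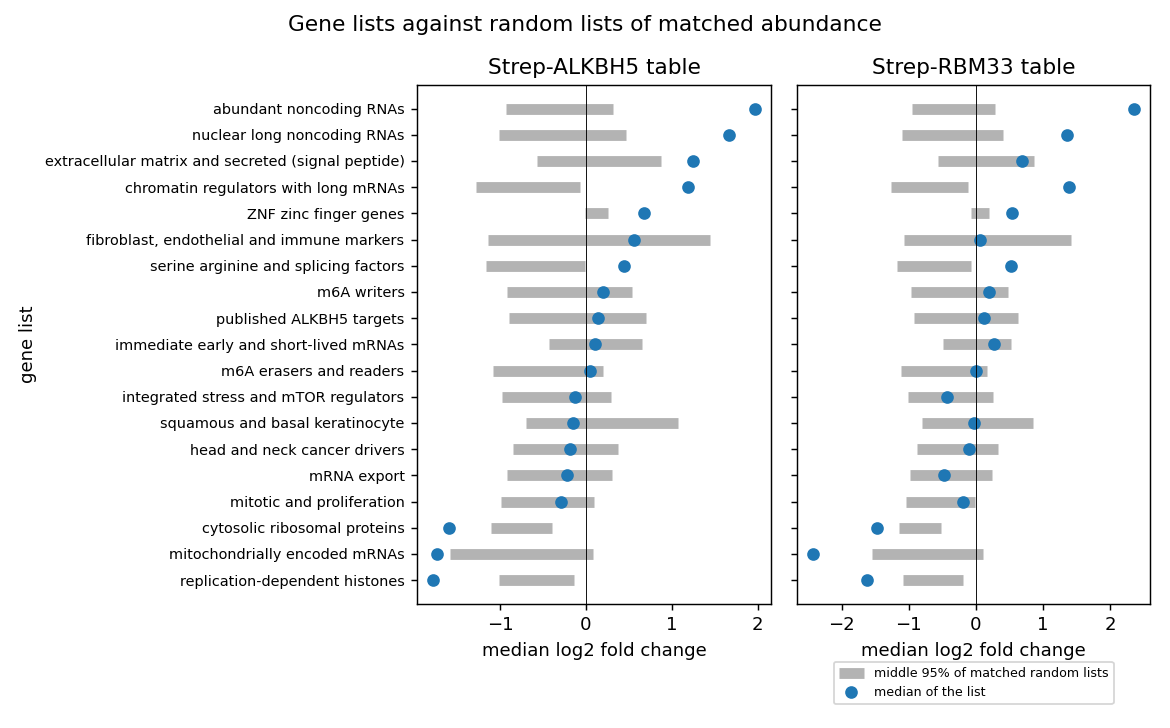
Median log2 fold change of each of the 19 gene lists in the authors' deposited tables for ALKBH5 and RBM33, beside the middle 95% of 10000 random lists matched on abundance. Noncoding RNA and chromatin regulator lists have medians above 1, and mitochondrial mRNAs, ribosomal protein mRNAs and histone mRNAs have medians below -1 in both tables.

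The m6A machinery and published ALKBH5 targets were examined as fixed lists because ALKBH5 removes m6A. Writers of the mark had 3 positive and 3 negative of 12 members in the authors' deposited table for ALKBH5 (3 and 3 adjusted over the list alone, adjusted p = 1 for either direction). The numbers were 5 and 3 in the authors' deposited table for RBM33 (5 and 3 adjusted over the list alone, adjusted p = 0.317 for positive calls). RBM15, an adaptor of the methyltransferase complex, stood at 1.77 and 1.65 and ZC3H13, another adaptor, at 0.77 and 0.94 in the authors' deposited tables for ALKBH5 and RBM33. METTL5, a methyltransferase of ribosomal RNA, had -1.21 and -1.53 in the authors' deposited tables. Erasers and readers had 3 positive and 4 negative of 18 members in each of the authors' deposited tables (3 and 4 adjusted over the list alone, adjusted p = 0.527 and 0.896 for positive calls). The reader YTHDC2 had 1.34 and 0.94 and HNRNPC -1.24 and -1.12 in the authors' deposited tables. Of the published ALKBH5 targets, 4 of 12 listed genes were positive and 2 negative for ALKBH5 in the authors' deposited table (4 and 2 adjusted over the list alone, adjusted p = 0.904 for positive calls). For RBM33, 4 were positive and 3 negative in the authors' deposited table (4 and 3 adjusted over the list alone, adjusted p = 0.79 for positive calls). FOXO1, a transcription factor, at 1.17 and 1.44 and PER1, a clock repressor, at 1.04 and 1.11 were positive in the authors' deposited tables. FOXM1, a transcription factor of the cell cycle, was negative there at -0.99 and -0.56.

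Other fixed lists bear on growth and stress. In the authors' deposited tables, head and neck cancer drivers had 5 positive and 5 negative of 20 members for ALKBH5 (4 and 5 adjusted over the list alone) and 5 and 6 for RBM33 (5 and 6 adjusted over the list alone). Neither passed the test (adjusted p = 0.904 and 1 for positive calls). The acetyltransferase gene EP300 was positive at 1.31 and 1.75 and the GTPase gene HRAS negative at -1.97 and -1.45 in the authors' deposited tables. Integrated stress and mTOR regulators had 4 positive and 8 negative of 18 members for ALKBH5 in the authors' deposited table (4 and 8 adjusted over the list alone, adjusted p = 0.364 for negative calls). For RBM33 the numbers in the authors' deposited table were 4 and 9 (4 and 10 adjusted over the list alone, adjusted p = 0.0786). XBP1, a transcription factor of the unfolded protein response, had -1.78 and -1.80 and RPTOR, a subunit of mTOR complex 1, 1.53 and 1.20 in the authors' deposited tables. Immediate early and short-lived mRNAs had 8 positive and 2 negative of 29 listed members in each of the authors' deposited tables (7 and 2 for ALKBH5 and 8 and 2 for RBM33 adjusted over the list alone). Negative calls were fewer than among other genes (Fisher's exact test, adjusted p = 0.0195 and 0.0306). Both calls were lost in the authors' deposited tables at a threshold of 0.01 (adjusted p = 0.0695 and 0.161) and with a minimum of 1 log2 unit (adjusted p = 0.424 and 0.451). Among genes of at least median abundance both were kept in the authors' deposited tables (Fisher's exact test, adjusted p = 0.0221 and 0.0278). FOSB, a subunit of the AP-1 factor, was positive at 2.39 and 3.99 and ATF3, a stress-induced factor, negative at -1.48 and -1.35 in the authors' deposited tables. For RBM33, mitotic and proliferation mRNAs had 5 positive and 10 negative of 27 members in the authors' deposited table (5 and 10 adjusted over the list alone, adjusted p = 0.479). For ALKBH5, export factor mRNAs had 5 positive and 8 negative of 19 members in the authors' deposited table (5 and 8 adjusted over the list alone, adjusted p = 0.386).

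Markers of cell type were counted as a check on the cells. Squamous and basal keratinocyte markers were listed for 10 of 25 genes in the authors' deposited tables, and the 15 not listed include TP63 and the basal keratins KRT5, KRT14 and KRT17. Of 12 markers of the embryonic kidney line HEK293, a list added after this was seen, 9 were listed in the authors' deposited tables (9 of 12 against 10 of 25, Fisher's exact test, p = 0.0789). Such a test compares chosen lists of symbols and does not measure which cells were used. The neurofilament genes NEFL and NEFM had an average log2 CPM of 8.10 and 7.72 in the authors' deposited table for ALKBH5 and 7.42 and 7.18 in that for RBM33. Those levels were above the most abundant squamous marker, DSP, at 6.86 and 6.93 in the authors' deposited tables. Of the 9 listed HEK293 markers 7 had at least median abundance in each of the authors' deposited tables, and PEG10 at 0.13 and -0.89 and PAX2 at 1.83 and 1.85 were low. At least median abundance was also reached by 6 of the 10 listed squamous markers in each of the authors' deposited tables. Of the 10 squamous markers listed, 2 were positive and 2 negative for ALKBH5 (2 and 2 adjusted over the list alone) and 2 and 3 for RBM33 (2 and 3 adjusted over the list alone) in the authors' deposited tables. Neither share of positive calls differed from that of other genes by the test (adjusted p = 0.904 and 1). DSP, a desmosome gene, was positive at 0.37 and 0.86, and PERP, a desmosome-associated gene, was negative at -1.44 and -1.48 in the authors' deposited tables. Fibroblast, endothelial and immune markers were listed for 5 of 21 genes in the authors' deposited tables. One of them, the collagen gene COL1A1, was positive in both of the authors' deposited tables, at 1.91 and 1.36 (1 adjusted over the list alone, adjusted p = 1).

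The design also asks whether the RNAs bound by ALKBH5 depend on RBM33. Libraries of Strep-ALKBH5 cells with RBM33 siRNA were not analysed here.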

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

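The alternatives of protein-coding genes only, identical rows counted once and the regressed trend were chosen after seeing the data. Of the call counts, overlaps, correlation and list counts, each recomputed under those alternatives that were run for it, 45 values stayed within 1.5 times the main value, 6 moved further and none reversed. Among genes of at least median abundance, positive calls numbered 2380 for ALKBH5 and 1978 for RBM33 and 1754 were shared, a setting that keeps fewer genes by construction. With a minimum of 1 log2 unit, negative calls numbered 2641 for ALKBH5 and 2732 for RBM33 and 2077 were shared, since small changes are then not counted. The ratio of shared positive calls to independent lists ranged from 2.93 to 4.05, and the Pearson r across genes from 0.815, with abundance, length and gene type regressed out, to 0.961 among genes of at least median abundance. The number of list calls ranged from 8 to 9 for ALKBH5 and from 7 to 10 for RBM33. Not run, for want of values per library, were another count tool, other scaling, filters or pseudocounts, other contrasts, leaving out replicates and splitting the vector libraries. The same holds for an estimated correlation between genes, regroupings of the samples, ALKBH5 against RBM33, and vector pull-down against input. Taking genes listed in either table changes nothing, as both list the same genes. No paired analysis was possible because the tables hold no values per library. Depth limits are unknown for the same reason.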

Other observations

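Tests chosen after the result was seen are those of the low-count filter, of the bead background and of short noncoding RNAs. The marker list of another cell line, the regression, the abundance match, the length match and the pseudogene pairs had their predictions written before the value they measure was seen.

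Pseudogenes and mitochondrial transfer RNAs were further groups outside the fixed lists. Unprocessed pseudogenes that are transcribed were positive for 173 and negative for 15 of 285 genes in the authors' deposited table for ALKBH5 (median 1.19) and 141 and 22 in that for RBM33 (median 0.99). Processed pseudogenes were positive for 71 and negative for 193 of 513 (median -0.91) and for 60 and 133 (median -0.49) in the authors' deposited tables. Among mitochondrial RNAs, the 12 heavy-strand mRNAs were all negative, with medians of -1.85 and -2.45, and 14 transfer RNAs of that strand had medians of -1.50 and -0.79 in the authors' deposited tables for ALKBH5 and RBM33. The 8 transfer RNAs of the light strand had medians of -0.02 and 0.50 and MT-ND6 had -0.05 and 0.06 in the authors' deposited tables; the strands were not tested against each other.

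Squamous markers that were not listed are the first pattern. A candidate explanation is libraries from another cell line: of 12 markers of the embryonic kidney line HEK293, written down before their listing was looked up, 9 were listed in both of the authors' deposited tables, where at most 4 would have counted against it. The neurofilament genes NEFL and NEFM had average log2 CPM of 8.10 and 7.72 and IGF2BP1, also in the list of m6A readers, 8.26 in the authors' deposited table for ALKBH5, against 6.86 for DSP, the most abundant squamous marker listed, but PEG10 at 0.13 and PAX2 at 1.83 were low there. The difference in listing was 9 of 12 against 10 of 25 (Fisher's exact test, p = 0.0789). That test compares symbols of chosen lists, which are not samples, so it cannot decide the source of the cells. How many of these genes UM-SCC-1 expresses was not measured here, so the source stays open. A low-count filter that removed well expressed genes is argued against, because the 1st percentile of listed genes was -0.17 log2 CPM in the authors' deposited table for ALKBH5. Loss of squamous identity in this culture was not tested.

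The agreement of both tables is the second pattern. A shared trend with abundance, listed gene length and gene type is argued against as the whole cause, because r was 0.82 after these were regressed out, although they took up 35.4% and 33.4% of the variance. Shared background of the beads cannot be told apart from shared targets: r = 0.872 would follow from either, and the vector pull-down that would decide it was not analysed here. Binding of ALKBH5 and RBM33 to the same RNAs therefore remains a possible explanation and untested.

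Negative values of ribosomal protein, histone and mitochondrial mRNAs are the third pattern. High abundance is argued against for ribosomal protein and histone mRNAs, whose medians were at percentile 0 of abundance-matched lists in both of the authors' deposited tables. For mitochondrial mRNAs the percentiles were 0.47 for ALKBH5 and 0 for RBM33, which cannot decide the question. Each bin of the match pools genes over a range of abundance. MT-CO1, MT-ND4 and MT-CO2 had average log2 CPM of 13.48, 12.86 and 12.32 in the authors' deposited table for ALKBH5. Genes drawn in place of mitochondrial mRNAs may have been much less abundant. A loss of all short RNAs is argued against too. The 68 noncoding RNAs of up to 400 bases that overlap no other listed gene had medians of 1.22 and 1.59 in the authors' deposited tables. Those are opposite in sign to the mRNAs whichever way the ratio runs. Loss of short mRNAs alone is not decided by them, because short RNA types differed. Small nuclear RNAs had medians of 1.45 and 2.03, microRNAs -0.24 and 0.24, and mitochondrial transfer RNAs -0.86 and -0.20 in the authors' deposited tables. The trend with listed gene length, histone part, stays possible, with percentiles of 4.81 and 37.74 among lists matched on listed length and abundance. Those matched lists had medians of -1.56 for ALKBH5 and -1.60 for RBM33. Whether mRNAs of the other negative groups were among them was not examined, so the match alone does not show a length effect. For the trend with listed gene length, ribosomal protein part, the higher percentile was 0.3. There the median of -1.59 lay below the matched -1.34 for ALKBH5. Length of the mRNA itself was not tested and stays open for all these groups, the match was not run for mitochondrial mRNAs, and no biological explanation was tested.

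Processed pseudogenes of ribosomal protein genes were negative for 60 and positive for 3 of 106 in the authors' deposited table for ALKBH5, and 45 and 2 in that for RBM33. Reads shared with their parent genes cannot be told apart from transcripts of their own: Pearson r across the pairs was 0.0719 and 0.172, and the medians of -1.37 and -1.07 stood above the parents' -1.86 and -1.62.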
